A study of Mus musculus with 17 samples.

How the data were processed

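Gene expression was measured on Affymetrix mouse arrays in 17 samples of 5 groups. The 13 leukemia arrays carry labels that name flow-sorted myeloid splenocytes (CD11b and Gr1 positive, CD3, CD4 and CD8 negative) of recipient mice given cells transformed with Myc and Bcl2. The transformed cells were LSK cells (lineage-negative, Sca1-positive, c-kit-positive marrow cells enriched for stem cells, 3 arrays), thymic DN2 cells (early T-cell progenitors, 5 arrays) or granulocyte-macrophage progenitors (GMP, 5 arrays). The other 4 arrays hold healthy thymic DN2 cells (2 arrays) and healthy marrow GMP (2 arrays). Groups and replicate numbers were taken from the labels and no array was regrouped. Nothing in the labels says that the replicates of a group are separate mice, so no p-value measures more than the spread between these samples. Fisher's test takes genes as its units and does not measure that spread.

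Per the labels' protocols, 300 ng of total RNA per array was labelled with a 3' IVT Express kit. The deposited values are RMA summaries on the log2 scale, made by the authors per probe set, as the submitters' processing notes state with the tools RMA and affy. Versions and parameters are not given in the sources used here, nor is it stated whether all arrays were normalized together. The table holds 45141 probe sets, of which 104 control probe sets were left out, and it holds no detection calls. Array medians ran from 3.80 to 3.86 and the values from 2.18 to 14.25. Close to the median the signal is background, so a log2 difference against a group at that level is compressed. The number of arrays limits the precision.

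The platform annotation listed 29449 probe sets, of which 28898 had 1 gene symbol and 551 had several. The 15588 probe sets it did not list, and those with several symbols, were not named. Of the probe sets with 1 symbol, 28689 matched on Entrez identifier to the RefSeq gene table of the assembly GRCm38.p6, which was used for current names only. Each gene was represented by the probe set with the highest mean over all arrays (17097 genes). A gene was tested if its highest group mean exceeded the median of all values, 3.83, which left 11625 genes.

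Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, with all 17 arrays in 1 fit with a mean per group. The tests were two-sided with Benjamini-Hochberg adjustment per comparison over all genes tested, and a gene was called at an adjusted p under 0.05. The 8 comparisons were the 3 between leukemia groups, the DN2-labelled and GMP-labelled leukemias against their healthy cells of origin, the healthy cells against each other, the DN2-labelled leukemia against healthy GMP, and the interaction. The interaction is the difference between leukemia and healthy cells for DN2 minus that for GMP. Tests, comparisons, gene lists and the rule for named genes were fixed before the data were examined. Named genes were Myc, Bcl2 and the genes of the sort, the 6 called genes with the largest rise and the 6 with the largest fall among those whose groups did not overlap in any array, and up to 4 members per list with the largest difference, called members first. Genes named outside this rule are marked as chosen after their values were seen.

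The 25 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists per comparison. Camera with an estimated correlation and fry were run beside it, and lists needed at least 3 measured members. Member calls come from the fit over all genes, with a second count adjusted over the list alone. The lists cover the T-cell receptor complex, T-lineage transcription factors, antigen receptor recombination, primary granules, late neutrophil genes, monocytes, myeloid transcription factors, MHC class II, B cells, NK cells, erythroid cells, platelets, mast cells, stem cells, Hoxa genes, Myc-induced ribosome biogenesis, the cell cycle, the Bcl2 family, the p53 pathway, the interferon response, glycolysis, immediate early genes, stroma, sex-linked genes, and the genes of the sort and transgenes. Some genes are on more than 1 list, and their names are not reported here.

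A lineage position was computed per array as the projection on the line from the healthy GMP mean (0) to the healthy DN2 mean (1). It used the 1072 genes called between the healthy groups with a fold of at least 2. Positions and within-group against between-group correlations were compared by exact two-sided permutation tests, adjusted over the 3 pairs of leukemia groups. Genes shared between comparisons were tested with Fisher's exact test. Principal components were taken over the genes tested.

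The procedure was tested on simulated arrays with the real gene means and spreads, in which 200 genes per comparison were changed. Each gene had 1 mean and 1 spread for all groups and was drawn independently of other genes. Unequal spreads between groups and correlation between genes were therefore not covered. Of 50 genes changed by a log2 of 1, 54% were called for DN2-labelled minus GMP-labelled leukemia, 52% for LSK-labelled minus GMP-labelled leukemia and 26% for the healthy groups. At a log2 of 2 the shares were 82%, 86% and 62%. Over all sizes of change together, 7 of 135 calls were false, 9 of 138 and 4 of 99. The alternatives fixed in advance changed the filter, the rule for several probe sets, the unit counted, the fold and significance thresholds, the prior variance, array weights, scaling, the arrays in the fit, the genes and measure of the position, the correlation within lists, the list test, a replicate block, and the leaving out of each replicate. Leaving out LSK-labelled arrays 2 and 3 together, and a Y-linked covariate, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.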

Results

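The series holds expression values for 13 leukemia arrays (3 labelled LSK-derived, 5 labelled DN2-derived, 5 labelled GMP-derived) and 4 arrays of healthy progenitors (2 DN2, 2 GMP). Values are log2 expression values per probe set, with 1 probe set per gene, and array medians from 3.80 to 3.86. Differences are log2 differences with their standard error (SE) from limma, group values are means with the standard deviation (SD), and 11625 genes were tested in each comparison. Genes are placed by symbol only, since no coordinates of the array's genome build were used here.

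The genes of the sort and of the transgenes show what each set of arrays holds. Itgam encodes CD11b, a positive marker of the sort beside Gr1. Ly6g, the gene listed for Gr1, was not among the genes tested, so Gr1 was not assessed. It had a mean of 9.52 ± 0.52 in the LSK-labelled arrays (SD, n = 3) and 9.05 ± 0.91 in the GMP-labelled arrays (SD, n = 5). In the DN2-labelled arrays it was 4.94 ± 2.14 (SD, n = 5), against 3.84 ± 0.18 in healthy DN2 (SD, n = 2). Arrays 1 and 3 had 7.17 and 7.38 and the other 3 had 3.24 to 3.47. Cd3e, a chain of the T-cell receptor complex that the sort excluded by its protein, was 8.41 ± 0.47 in the DN2-labelled arrays, 5.13 ± 0.08 in the GMP-labelled arrays and 5.12 ± 0.19 in the LSK-labelled arrays. Cd4 lay between 3.54 and 3.94 and Cd8a between 3.44 and 3.98 in the 5 group means. Cd3d, another CD3 chain picked after its values were seen, was 12.36 ± 0.16 in the DN2-labelled arrays. In the GMP-labelled arrays Cd3d was 7.61 ± 0.68, against 3.65 ± 0.29 in healthy GMP, while Cd3g was 3.51 ± 0.18. At the RNA level, Cd3e in all 5 DN2-labelled arrays and Itgam in 3 of them go against the myeloid sort on their label, while Cd4 does not. The sort was by protein, which these arrays do not measure, and Cd3d RNA was raised in the GMP-labelled arrays too. Cd8a was 4.38, 4.43 and 4.06 at its 3 probe sets in DN2-labelled array 3 and up to 4.72 in array 5, against at most 3.66 in any LSK-labelled or GMP-labelled array. Every direction given for the DN2-labelled arrays is for arrays with that label.

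Mycn, a relative of Myc, rose over healthy cells by 7.51 ± 1.51 in the DN2-labelled arrays (SE, n = 5 and 2, adjusted p = 0.0021) and by 8.28 ± 1.51 in the GMP-labelled arrays (adjusted p = 0.0015). Its mean was 11.87 ± 0.20 in the DN2-labelled and 12.55 ± 0.43 in the GMP-labelled arrays, against 4.36 ± 0.22 and 4.27 ± 0.44 in healthy DN2 and GMP. Myc itself was lower than in healthy cells, by −4.40 ± 0.26 in the DN2-labelled arrays (SE, adjusted p = 1.21e-08) and by −4.46 ± 0.26 in the GMP-labelled arrays (adjusted p = 2.18e-08). The labels name Myc, and which Myc family gene the vector carried is not given in the sources used here. The arrays do not separate a transgene from the mouse's own gene. Bcl2, the second transgene, rose by 4.56 ± 1.03 in the GMP-labelled arrays over healthy GMP (adjusted p = 0.0063). Between the DN2-labelled arrays and healthy DN2 it differed by 2.79 ± 1.03, which did not pass (adjusted p = 0.0635). The arrays of these groups did not overlap, with 9.25 to 9.94 in the DN2-labelled arrays and 6.99 and 6.78 in healthy DN2. The SE comes from a spread shared by all groups, and the SD was 3.14 in the LSK-labelled arrays. A second Bcl2 probe set went the other way, with means of 6.22 in the DN2-labelled and 3.83 in the GMP-labelled arrays against 9.64 and 8.76 in the healthy groups, and whether either probe set lies within the transgene was not analysed here. Among the LSK-labelled arrays, array 1 had Mycn at 12.82 and Bcl2 at 11.30. Array 2 had 4.91 and 6.75 and array 3 had 4.22 and 5.27, which is near the healthy level.

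**Figure D1:**
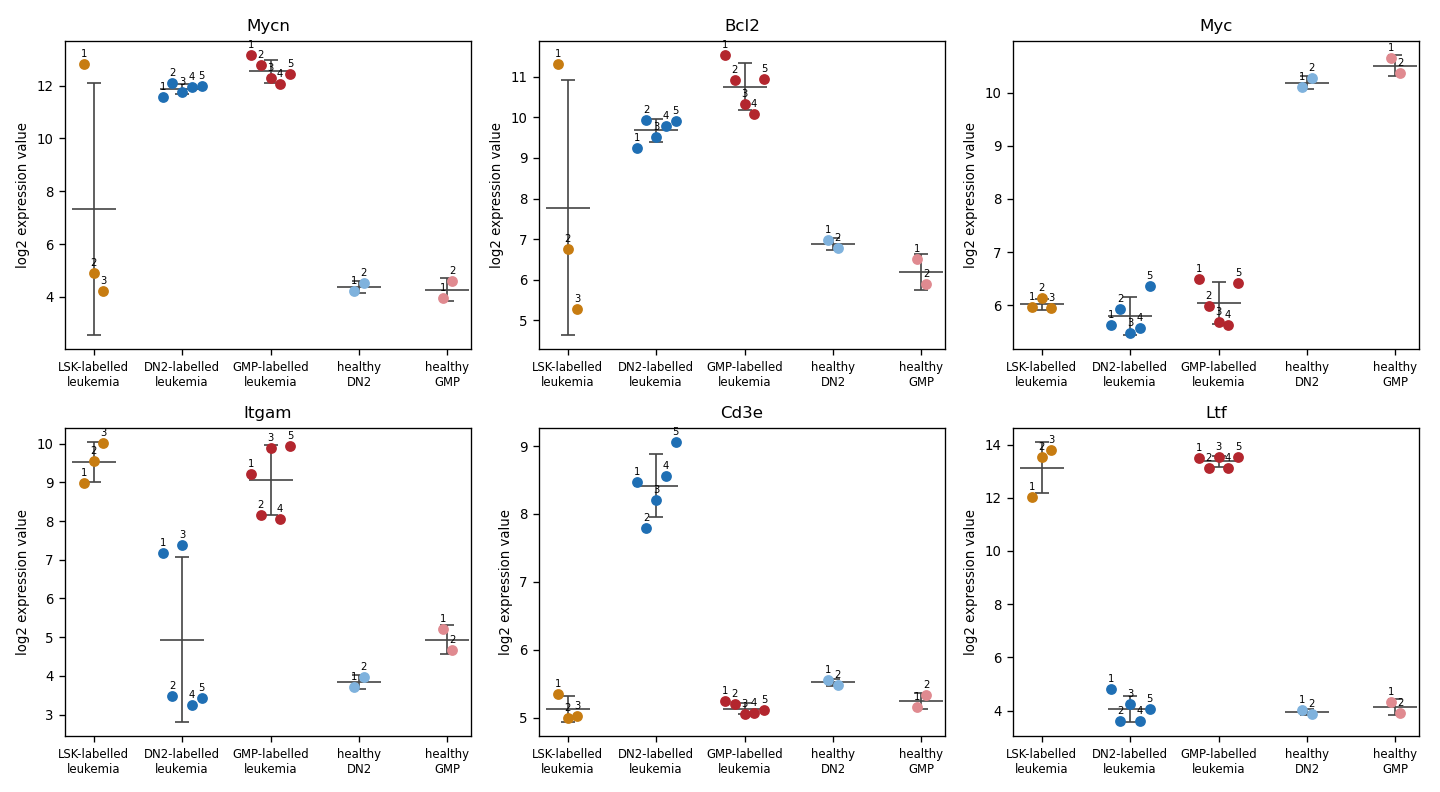
Log2 expression values of Mycn, Bcl2, Myc, Itgam, Cd3e and Ltf in each array (points with replicate numbers) of the 5 groups; bars are the group mean ± SD. Mycn was 4.91 and 4.22 in LSK-labelled arrays 2 and 3, and Itgam was 3.24 to 3.47 in 3 of the 5 DN2-labelled arrays.

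Arrays of a group correlated at 0.940 to 0.984 among the DN2-labelled, 0.933 to 0.990 among the GMP-labelled and 0.907 to 0.982 among the LSK-labelled leukemias. The last range overlaps that between LSK-labelled and GMP-labelled arrays, 0.841 to 0.909. Mean correlations over all genes tested were 0.796 between DN2-labelled and GMP-labelled leukemias, 0.784 between LSK-labelled and DN2-labelled, and 0.883 between LSK-labelled and GMP-labelled. The DN2-labelled arrays correlated with healthy DN2 at 0.876 and the GMP-labelled arrays with healthy GMP at 0.880, and the 2 healthy groups with each other at 0.911. These are correlations across genes, and genes are not independent replicates. Values were then centred per gene over the leukemia arrays. The mean correlation within groups exceeded that between groups by 1.28 for DN2-labelled and GMP-labelled arrays (exact permutation p = 0.0079). The excess was 1.16 for DN2-labelled and LSK-labelled and 0.499 for LSK-labelled and GMP-labelled arrays (exact permutation p = 0.0179 for each). Adjusted over the 3 pairs, each p was 0.0179, and each raw exact p was the smallest its design allows.

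**Figure D2:**
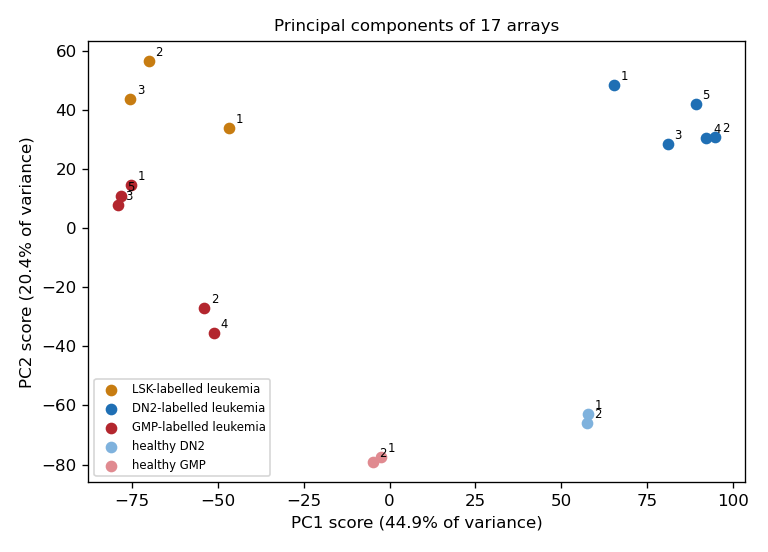
Scores of the 17 arrays on the first and second principal components (44.9% and 20.4% of the variance), coloured by group with replicate numbers. The DN2-labelled leukemias lie with healthy DN2 on the positive side of the first component, and the LSK-labelled and GMP-labelled leukemias on the negative side.

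The comparison of DN2-labelled with GMP-labelled leukemia asks whether the cell of origin leaves a difference between leukemias made with the same pair of oncogenes. Neutrophil granule genes were lower in the DN2-labelled arrays. Camp, an antimicrobial peptide of secondary granules, differed by −9.68 ± 0.31 (SE, n = 5 and 5, adjusted p = 4.59e-12). Olfm4 differed by −9.65 ± 0.23 (adjusted p = 4.06e-13), Lcn2 by −9.40 ± 0.31 (adjusted p = 6.14e-12) and Ltf, lactoferrin, by −9.31 ± 0.30 (adjusted p = 6.14e-12). None of the 4 overlapped between the arrays of the 2 groups. All 18 measured late neutrophil genes fell (18 adjusted over the list alone, median −8.49, camera adjusted p = 4.02e-19; adjusted p = 0.0421 with an estimated correlation). Of 8 primary granule genes 7 fell and 1 rose (adjusted over the list alone 7 and 1; adjusted p = 2.66e-04; adjusted p = 0.280 with an estimated correlation). Among them Ms4a3 differed by −8.10 ± 0.61 and Mpo, myeloperoxidase, by −6.73 ± 1.06. The primary granule mean was 11.54 and 11.60 in GMP-labelled arrays 2 and 4, 8.49 to 9.17 in the other 3 and 4.76 to 5.06 in the DN2-labelled arrays. The myeloid regulators Cebpd (−7.79 ± 0.50), Nfe2 (−5.68 ± 0.33) and Spi1 (−5.03 ± 0.43) also fell. The list of myeloid transcription factors as a whole was not called (5 of 12 lower, 1 higher; 6 and 1 adjusted over the list alone; adjusted p = 0.134).

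Genes of T cells and NK cells were higher in the DN2-labelled arrays. Of 16 measured genes of the T-cell receptor complex and its signalling, 15 rose (15 adjusted over the list alone, median 5.93, adjusted p = 2.77e-20; adjusted p = 6.16e-04 with an estimated correlation). Among them Sh2d1a rose by 8.19 ± 0.20, Cd3g by 7.96 ± 0.27 and Cd28 by 7.64 ± 0.26. All 12 measured NK and innate lymphoid genes rose (12 adjusted over the list alone, adjusted p = 3.41e-09; adjusted p = 0.0607 with an estimated correlation). The granzyme Gzma rose by 8.46 ± 0.47, the receptor Klrd1 by 8.16 ± 0.45 and the transcription factor Eomes by 7.18 ± 0.24. Of 14 T-lineage transcription factors and Notch targets, 8 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 9.74e-04; adjusted p = 0.0607 with an estimated correlation), including Bcl11b (4.72 ± 0.68) and Gata3 (3.86 ± 0.14). Ms4a4b, at 9.44 ± 0.34, had the largest rise among genes without overlap between the groups.

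Cell cycle and p53 pathway genes were lower in the DN2-labelled than in the GMP-labelled arrays. Of 27 cell cycle genes 18 fell and 1 rose (19 and 1 adjusted over the list alone, adjusted p = 9.74e-04; adjusted p = 0.771 with an estimated correlation), for example Cdk1 by −2.25 ± 0.53. DN2-labelled array 3 stood apart with a cell cycle mean of 9.15, within the GMP-labelled range of 8.46 to 9.56, while the other 4 lay at or under 7.97. Of 13 p53 pathway genes 9 fell (10 adjusted over the list alone, adjusted p = 3.69e-04; adjusted p = 0.308 with an estimated correlation), including the cell cycle inhibitor Cdkn1a (−4.51 ± 0.66) and Perp (−4.77 ± 1.02). Of 18 monocyte genes 7 fell (7 adjusted over the list alone, adjusted p = 0.0243; adjusted p = 0.724 with an estimated correlation). DN2-labelled array 1 stood apart with a monocyte mean of 6.81, within the GMP-labelled range of 6.31 to 7.41, while the other 4 lay at 4.31 to 5.08. The Myc-induced ribosome biogenesis list was not called (1 of 22 higher, Rrp12 by 0.79 ± 0.26, and 0 by limma adjusted over the list alone, with 2 at an unadjusted p under 0.05; adjusted p = 0.879). Glycolysis (6 of 11 lower, 1 higher, the same counts adjusted over the list alone) and the Bcl2 family (5 of 12 lower, 1 higher; 6 and 1 adjusted over the list alone) were not called either (adjusted p = 0.0823 for each). Nor were erythroid genes (1 of 10 higher, 1 adjusted over the list alone, adjusted p = 0.882), stroma (2 of 5 higher, 2 adjusted over the list alone, adjusted p = 0.274) or the genes of the sort and transgenes (2 of 9 higher, 2 lower, the same counts adjusted over the list alone, adjusted p = 0.843). Of the 4 sex-linked genes limma called 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.998, fry adjusted p = 0.869). Over all genes 4628 were called, 2438 higher and 2190 lower (2762 with a fold of at least 2), and 8 of the 25 lists. All 5 DN2-labelled arrays are in doubt at Cd3e, so this count cannot be run without them.

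**Figure D3:**
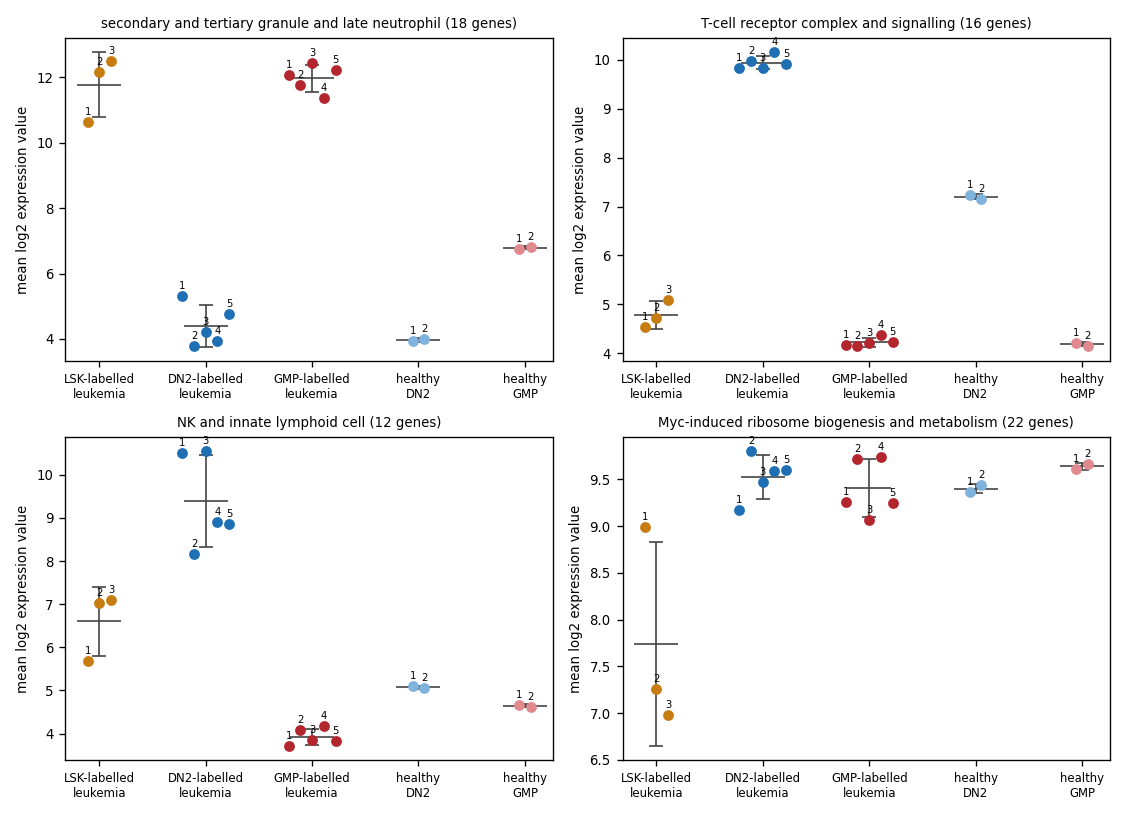
Mean log2 expression value per array of late neutrophil genes (18), T-cell receptor genes (16), NK and innate lymphoid genes (12) and Myc-induced ribosome biogenesis genes (22); points are arrays with replicate numbers, bars the group mean ± SD. The DN2-labelled arrays had a mean of 4.40 for late neutrophil genes, against 11.97 in the GMP-labelled arrays, and ribosome biogenesis was 7.26 and 6.97 in LSK-labelled arrays 2 and 3.

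The DN2-labelled and LSK-labelled leukemias were compared to ask the same of the stem-cell-enriched origin. Camp (−9.46 ± 0.35, n = 5 and 3, adjusted p = 6.61e-11) and Ngp (−9.20 ± 0.41, adjusted p = 4.30e-10) were lower in the DN2-labelled arrays. All 18 late neutrophil genes fell (18 adjusted over the list alone, adjusted p = 4.96e-18; adjusted p = 0.0486 with an estimated correlation). Gzmk (7.86 ± 0.24), Cd3g (7.67 ± 0.31) and Sh2d1a (7.44 ± 0.23) were higher. Of the 16 T-cell receptor genes 15 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 3.26e-15; adjusted p = 0.0026 with an estimated correlation). Of 12 NK genes 7 rose (7 adjusted over the list alone, adjusted p = 9.39e-04; adjusted p = 0.265 with an estimated correlation).

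Ribosome biogenesis and several lists of other blood cells also separated the DN2-labelled from the LSK-labelled arrays, beside the low Mycn of LSK-labelled arrays 2 and 3 (4.91 and 4.22). Of 22 ribosome biogenesis genes 17 rose, such as Pus7 by 4.19 ± 0.50 (20 adjusted over the list alone, adjusted p = 7.80e-06; adjusted p = 0.364 with an estimated correlation). Of 12 MHC class II and dendritic cell genes 9 fell (10 adjusted over the list alone, adjusted p = 7.99e-04; adjusted p = 0.287 with an estimated correlation). Of 13 interferon response genes 8 fell (9 adjusted over the list alone, adjusted p = 0.0022; adjusted p = 0.429 with an estimated correlation). Monocyte (13 of 18), primary granule (7 of 8), B-cell (6 of 10) and mast cell (6 of 7) genes fell too. Adjusted over the list alone the counts were 14, 7, 6 and 6, with adjusted p = 2.70e-06, 7.00e-04, 0.0028 and 0.0028. Those 4 lists had adjusted p = 0.265, 0.265, 0.246 and 0.200 with an estimated correlation. Myeloid transcription factors (5 of 12 lower, 2 higher, the same counts adjusted over the list alone, adjusted p = 0.0174), the cell cycle (15 of 27 lower, 3 higher; 17 and 3 adjusted over the list alone; adjusted p = 0.0065) and the Bcl2 family (5 of 12 lower, 1 higher; 8 and 1 adjusted over the list alone; adjusted p = 0.0146) were called as lower. They had adjusted p = 0.265, 0.623 and 0.124 with an estimated correlation.

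Without LSK-labelled arrays 2 and 3 the DN2-labelled arrays are set against LSK-labelled array 1 alone, which is assumed to vary like the other groups, so fewer genes can be called. The median difference of ribosome biogenesis genes went from 1.76 to 0.62 (4 of 22 called), of MHC class II genes from −2.35 to −1.07 (2 of 12) and of myeloid transcription factors from −2.23 to −0.40 (4 of 12 lower, 2 higher). For interferon response genes it went from −2.44 to −1.42, and limma called 0 of 13, with 2 at an unadjusted p under 0.05. These 4 lists were then not called (adjusted p = 0.0685 for each), nor was the mast cell list (−1.10 to −0.42, 1 of 7, adjusted p = 0.0572). Monocyte (−4.14 to −1.45, 6 of 18), primary granule (−5.33 to −2.83, 3 of 8) and B-cell genes (−1.04 to −0.27, 2 of 10) stayed called as lists (adjusted p = 0.0013, 0.0066 and 0.0307). So did the cell cycle (−1.28 to −1.49, 2 of 27, adjusted p = 0.0030) and the Bcl2 family (−0.70 to −0.45, 3 of 12 lower, 1 higher, adjusted p = 0.0252).

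DN2-labelled arrays 1 and 3 stood apart from the other 3 in several of these lists. The MHC class II mean was 7.48 in array 1 and 4.29 to 5.72 in the other 4, against 6.59, 8.57 and 8.42 in the LSK-labelled arrays. The interferon response mean was 8.23 and 8.69 in arrays 1 and 3 and 5.58 to 6.23 in the other 3, against 8.47, 10.77 and 8.98. In array 1 the monocyte mean was 6.81 and that of myeloid transcription factors 8.02, with 4.31 to 5.08 and 6.85 to 7.12 in the other 4 and at least 7.47 and 8.40 in the LSK-labelled arrays. The cell cycle mean of array 3 (9.15) lay above all 3 LSK-labelled arrays (8.32 to 8.94). Y-linked Eif2s3y was 8.93 to 9.90 in the LSK-labelled arrays. Among the DN2-labelled arrays it was high only in array 2 (10.05, others 2.72 to 2.92). Y-linked signal and the LSK label were thus largely confounded. Over all genes 5514 were called, 3296 higher and 2218 lower (3490 with a fold of at least 2), against a median of all genes shifted by 0.11. With the Y-linked covariate the count was 4593. Without the 2 arrays the count was 3172, of which 2659 were among the 5514.

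The LSK-labelled and GMP-labelled leukemias set the 2 marrow origins against each other. Jchain, the joining chain of immunoglobulins, was higher in the LSK-labelled arrays by 7.84 ± 0.91 (SE, n = 3 and 5, adjusted p = 4.51e-05). Igkj1, an immunoglobulin segment, was higher by 7.64 ± 1.25 (adjusted p = 6.00e-04) and Gzma by 7.54 ± 0.55 (adjusted p = 5.11e-07). Penk, the precursor of enkephalin peptides, differed by −5.44 ± 0.24 (adjusted p = 4.69e-09), Stfa3 by −5.62 ± 0.35 and the sodium channel subunit Scn2b by −5.41 ± 0.27, each without overlap between the groups. With LSK-labelled array 1 alone, in which Mycn was high, Jchain differed by 9.46, Gzma by 6.88 and Penk by −5.82. Late neutrophil genes were not called as a list (1 of 18 lower, Olfm4 by −2.74 ± 0.27; 1 adjusted over the list alone; adjusted p = 0.753), with a median of −0.05. Their mean was 10.64 in LSK-labelled array 1, 12.16 and 12.51 in arrays 2 and 3, and 11.38 to 12.43 in the GMP-labelled arrays. With array 1 alone, assumed to vary like the other groups, the median was −1.32 and the list was called as lower (5 of 18, adjusted p = 0.0015). Primary granule genes, not called with all arrays (1 of 8 lower, 1 adjusted over the list alone, median −1.06, adjusted p = 0.628), were then called as lower too (2 of 8, median −2.88, adjusted p = 0.0152).

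The MHC class II, interferon response, NK and B-cell lists were higher in the LSK-labelled than in the GMP-labelled arrays. So were the immediate early, monocyte, T-cell receptor and mast cell lists. The ribosome biogenesis and p53 pathway lists were lower, beside the low Mycn of LSK-labelled arrays 2 and 3 (4.91 and 4.22). None of these 10 lists was called with an estimated correlation. MHC class II and dendritic cell genes rose in 11 of 12 (11 adjusted over the list alone, adjusted p = 2.38e-07), with H2-Aa at 5.23 ± 1.30. Interferon response genes rose in 11 of 13 (13 adjusted over the list alone, adjusted p = 8.57e-07), with Mx1 at 4.42 ± 0.99. NK genes rose in 8 of 12 (9 adjusted over the list alone, adjusted p = 3.39e-07) and B-cell genes in 7 of 10 (8 adjusted over the list alone, adjusted p = 4.84e-05). Ribosome biogenesis genes fell in 18 of 22 (21 adjusted over the list alone, adjusted p = 1.44e-08), with Dkc1 at −3.14 ± 0.41, and p53 pathway genes in 8 of 13 (8 adjusted over the list alone, adjusted p = 9.24e-05). The p53 pathway mean was 8.67 in LSK-labelled array 1, within the GMP-labelled range of 8.64 to 9.92, and 7.12 and 6.70 in arrays 2 and 3. Immediate early (5 of 11, 8 adjusted over the list alone, adjusted p = 9.87e-05), monocyte (8 of 18, 8 adjusted over the list alone, adjusted p = 5.19e-04), T-cell receptor (8 of 16 higher, 1 lower, the same counts adjusted over the list alone, adjusted p = 6.63e-04) and mast cell genes (3 of 7, 4 adjusted over the list alone, adjusted p = 0.0024) rose. The immediate early mean of LSK-labelled array 3 (10.93) lay under that of GMP-labelled array 4 (10.98). In the order of their counts, the 10 lists had adjusted p = 0.192, 0.311, 0.191, 0.191, 0.334, 0.307, 0.334, 0.334, 0.191 and 0.191 with an estimated correlation.

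Over all genes 3108 were called between the LSK-labelled and GMP-labelled arrays, 1194 higher and 1914 lower (1867 with a fold of at least 2). With the Y-linked covariate the count was 2495. Y-linked Eif2s3y was 8.93 to 9.90 in the LSK-labelled arrays. Among the GMP-labelled arrays it was high only in array 2 (9.90, others 2.75 to 2.84), so here too Y-linked signal and the LSK label were largely confounded. Without LSK-labelled arrays 2 and 3 the count was 1374, of which 873 were among the 3108, and without LSK-labelled array 2 alone it was 1889. Without the 2 arrays the LSK-labelled group is 1 array, assumed to vary like the other groups, so fewer genes can be called. The median difference of interferon response genes went from 3.29 to 2.54, and limma called 0 of 13, with 3 at an unadjusted p under 0.05, while the list stayed called (adjusted p = 0.0012). MHC class II (3.65 to 2.35, 1 of 12), NK (1.90 to 1.10, 4 of 12) and B-cell genes (1.40 to 0.47, 3 of 10) also stayed called as lists (adjusted p = 6.18e-04, 3.27e-04 and 0.0015). So did immediate early (1.37 to 1.28, 2 of 11) and T-cell receptor genes (0.49 to 0.27, 1 of 16; adjusted p = 5.73e-04 and 0.0231). Ribosome biogenesis (−1.36 to −0.42, 3 of 22) and p53 pathway genes (−1.41 to −0.98, 4 of 13) were not called as lists (adjusted p = 0.132 for each). Nor were monocyte genes (1.69 to 0.43, 1 of 18 higher, 1 lower, adjusted p = 0.216) or mast cell genes (1.13 to 0.46, 0 of 7 by limma, 1 at an unadjusted p under 0.05, adjusted p = 0.205). With only these 2 groups in the fit the count was 1659.

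The DN2-labelled leukemia was compared with healthy DN2 cells, the progenitor on its label. T-cell receptor genes were higher in the leukemia, with Cd2 at 7.91 ± 0.26 (SE, n = 5 and 2, adjusted p = 9.23e-12) and Cd3d at 7.09 ± 0.46 (adjusted p = 2.83e-08). Of the 16, 11 rose (12 adjusted over the list alone, adjusted p = 1.84e-11; adjusted p = 0.0083 with an estimated correlation). NK genes rose in 8 of 12 (8 adjusted over the list alone, adjusted p = 2.50e-09; adjusted p = 0.0682 with an estimated correlation), among them Klrk1 (7.52 ± 0.71) and Klrb1c (7.29 ± 0.44). Dntt, the terminal transferase of receptor gene recombination, differed by −8.96 ± 0.17 (adjusted p = 2.78e-14). The progenitor genes Cpa3 (−9.01 ± 0.29), Cd34 (−6.31 ± 0.18) and Kit (−6.43 ± 0.88) fell too. Recombination genes fell in 5 of 11 and rose in 1 (5 and 2 adjusted over the list alone, adjusted p = 0.0016; adjusted p = 0.157 with an estimated correlation). Hoxa genes and cofactors fell in 4 of 5 (4 adjusted over the list alone, adjusted p = 9.97e-04; adjusted p = 0.0522 with an estimated correlation) and stem cell genes in 4 of 11 (4 adjusted over the list alone, adjusted p = 0.0024; adjusted p = 0.109 with an estimated correlation).

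Cell cycle genes fell in 24 of 27 against healthy DN2 (24 adjusted over the list alone, adjusted p = 1.04e-08; adjusted p = 0.550 with an estimated correlation), with Rrm2 at −3.02 ± 0.73. DN2-labelled array 3 stood apart with a mean of 9.15, close to healthy DN2 (9.77 and 9.78), while the other 4 lay at or under 7.97. Late neutrophil genes differed by a median of 0.18, and limma called 0 of 18 (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, camera adjusted p = 0.491, fry adjusted p = 0.626). Cybb had the largest difference among them, 2.34 ± 1.36 (adjusted p = 0.254). Primary granule genes were not called as a list by camera, but their mean was lower in the leukemia. It was 4.84 ± 0.12 (SD, n = 5), against 6.82 ± 0.10 in healthy DN2 (SD, n = 2). Mpo had means of 3.52 ± 0.14 in the leukemia and 10.59 ± 0.02 in healthy DN2. Over all genes 2695 were called, 1103 higher and 1592 lower (1916 with a fold of at least 2). The count was 1236 without healthy DN2 replicate 2 and 1252 without replicate 1, where the remaining healthy array is assumed to vary like the other groups, and 5885 with array weights.

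The GMP-labelled leukemia was compared with healthy GMP, the myeloid progenitor on its label. Late neutrophil genes were higher in the leukemia, with Olfm4 at 9.83 ± 0.31 (SE, n = 5 and 2, adjusted p = 2.87e-11), Ltf at 9.24 ± 0.40 (adjusted p = 9.97e-10) and Mmp8, neutrophil collagenase, at 8.18 ± 0.75 (adjusted p = 2.71e-06). Of the 18, 14 rose (15 adjusted over the list alone, adjusted p = 7.82e-20; adjusted p = 0.0235 with an estimated correlation). Genes of the p53 pathway rose in 9 of 13 (12 adjusted over the list alone, adjusted p = 2.69e-10; adjusted p = 0.0526 with an estimated correlation), among them Trp53inp1 (6.06 ± 0.47) and Zmat3 (4.89 ± 0.58). Mast cell genes fell in 5 of 7 (5 adjusted over the list alone, adjusted p = 3.14e-06; adjusted p = 0.0235 with an estimated correlation), including Cpa3 (−6.91 ± 0.29). Hoxa genes and cofactors fell in 4 of 5 (4 adjusted over the list alone, adjusted p = 1.14e-05; adjusted p = 0.0196 with an estimated correlation), including Meis1 (−3.45 ± 0.23). Stem cell genes fell in 6 of 11 (7 adjusted over the list alone, adjusted p = 4.19e-04; adjusted p = 0.0521 with an estimated correlation), including Cd34 (−7.14 ± 0.18).

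Platelet genes fell in 3 of 8 against healthy GMP (4 adjusted over the list alone, adjusted p = 0.0116; adjusted p = 0.0808 with an estimated correlation), with Pf4 at −5.28 ± 0.22. Cell cycle genes fell in 7 of 27 (7 adjusted over the list alone, adjusted p = 0.0072; adjusted p = 0.786 with an estimated correlation), with Mcm3 at −1.93 ± 0.46. Mpo differed by −3.67 ± 1.40, which did not pass (adjusted p = 0.0753), and primary granule genes were not called as a list (1 of 8 lower, 1 adjusted over the list alone, adjusted p = 0.151). The GMP-labelled arrays were of 2 kinds here, with primary granule means of 11.54 and 11.60 in arrays 2 and 4 and 8.49 to 9.17 in the other 3, against 12.30 and 12.37 in healthy GMP. Over all genes 2463 were called, 940 higher and 1523 lower (1755 with a fold of at least 2), against a median of all genes shifted by −0.12. The count was 890 without healthy GMP replicate 1, 848 without replicate 2 and 6054 with array weights.

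Healthy DN2 and healthy GMP were compared for the lineage difference between the normal starting cells. Dntt (8.70 ± 0.20, n = 2 and 2, adjusted p = 7.76e-13) and the T-lineage regulator Bcl11b (7.84 ± 1.08, adjusted p = 1.72e-04) were higher in DN2. The granule genes Ms4a3 (−9.78 ± 0.96, adjusted p = 6.15e-06) and Prtn3 (−9.45 ± 0.98, adjusted p = 1.02e-05) were lower. T-cell receptor genes rose in 12 of 16 (13 adjusted over the list alone, adjusted p = 2.03e-18) and T-lineage transcription factors in 10 of 14 (10 adjusted over the list alone, adjusted p = 7.04e-12). Recombination genes rose in 6 of 11 (7 adjusted over the list alone, adjusted p = 5.60e-07). Primary granule genes fell in 5 of 8 (5 adjusted over the list alone, adjusted p = 1.35e-05; adjusted p = 0.164 with an estimated correlation). Late neutrophil genes fell in 9 of 18 (9 lower and 1 higher adjusted over the list alone, adjusted p = 2.25e-05; adjusted p = 0.297 with an estimated correlation). Mast cell genes fell in 5 of 7 and rose in 1, platelet genes fell in 4 of 8 and glycolysis genes in 3 of 11 (adjusted over the list alone 5 and 1, 4, and 5; adjusted p = 1.91e-04, 0.0031 and 0.0031). These 3 lists and the T-cell receptor, T-lineage and recombination lists were also called with an estimated correlation. Monocyte genes fell in 2 of 18 (9 adjusted over the list alone, adjusted p = 0.0036) and immediate early genes rose in 3 of 11 (5 adjusted over the list alone, adjusted p = 0.0023), each with adjusted p = 0.538 with an estimated correlation. Over all genes 1300 were called, 672 higher and 628 lower (1072 with a fold of at least 2). The count was 631 without healthy DN2 replicate 1, 666 without replicate 2, 785 without healthy GMP replicate 1 and 602 without replicate 2. It was 5439 with array weights and 5326 with only these groups in the fit.

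Against healthy GMP, the DN2-labelled leukemia had higher T-cell receptor genes in 16 of 16 (16 adjusted over the list alone, adjusted p = 9.16e-26; adjusted p = 1.87e-04 with an estimated correlation), with Cd3d at 8.71 ± 0.46. Primary granule genes fell in 7 of 8 (7 adjusted over the list alone, adjusted p = 9.25e-06; adjusted p = 0.151 with an estimated correlation), with Mpo at −10.39 ± 1.40 (n = 5 and 2, adjusted p = 5.39e-05). T-lineage transcription factors rose in 7 of 14, and mast cell genes (6 of 7) and Hoxa genes and cofactors (4 of 5) fell (adjusted over the list alone 10 higher and 1 lower, 6, and 4; adjusted p = 9.74e-06, 5.90e-06 and 1.10e-04). These 3 lists were called with an estimated correlation too. NK (7 of 12), p53 pathway (5 of 13) and immediate early genes (5 of 11) rose (8, 5 and 5 adjusted over the list alone; adjusted p = 1.52e-08, 0.0226 and 0.0054). They had adjusted p = 0.0532, 0.524 and 0.524 with an estimated correlation. Late neutrophil (8 of 18), platelet (5 of 8), stem cell (6 of 11, with 1 higher) and cell cycle genes (24 of 27) fell (adjusted over the list alone 9, 5, 6 with 1 higher, and 24; adjusted p = 0.0029, 0.0071, 0.0138 and 2.46e-07). They had adjusted p = 0.490, 0.0757, 0.151 and 0.475 with an estimated correlation. The comparison measures how far this leukemia lies from a normal myeloid progenitor, and 3805 genes were called, 1584 higher and 2221 lower (2655 with a fold of at least 2). The count was 2231 without healthy GMP replicate 1, 1954 without replicate 2 and 6249 with array weights.

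The interaction tests whether the leukemias differ from their healthy cells in unlike ways. The interaction was positive for 10 of 16 T-cell receptor genes and negative for 1 (12 and 1 adjusted over the list alone, adjusted p = 1.69e-11; adjusted p = 0.0091 with an estimated correlation), with Cd2 at 8.13 ± 0.37. It was negative for 11 of 18 late neutrophil genes (12 adjusted over the list alone, adjusted p = 5.92e-14; adjusted p = 0.0723 with an estimated correlation), with Olfm4 at −9.66 ± 0.43. It was positive for 7 of 12 NK genes (9 adjusted over the list alone, adjusted p = 3.22e-10; adjusted p = 0.0723 with an estimated correlation). It was negative for 6 of 13 p53 pathway genes (6 adjusted over the list alone, adjusted p = 3.00e-05; adjusted p = 0.170 with an estimated correlation) and for 4 of 11 recombination genes (5 adjusted over the list alone, adjusted p = 6.14e-05; adjusted p = 0.0746 with an estimated correlation). T-lineage factors (2 of 14 positive, 5 negative; 2 and 6 adjusted over the list alone) and the cell cycle (1 of 27 negative, E2f1 at −1.24 ± 0.38; 0 by limma adjusted over the list alone, 6 at an unadjusted p under 0.05) were called as negative (adjusted p = 0.0244 and 0.0058). Platelet (3 of 8), mast cell (3 of 7, with 1 negative) and stroma genes (1 of 5, Krt8 at 1.68 ± 0.24) were called as positive (adjusted over the list alone 3, 4 with 1 negative, and 2; adjusted p = 0.0399, 0.0139 and 0.0408). These 5 lists had adjusted p = 0.159, 0.798, 0.159, 0.167 and 0.153 with an estimated correlation, and without the filter on dim probe sets the stroma list was not called (adjusted p = 0.216). Over all genes 1473 were called, 743 positive and 730 negative. The count was 821 without healthy DN2 replicate 1, 782 without replicate 2, 912 without healthy GMP replicate 1 and 804 without replicate 2. It was 5243 with array weights.

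On the line from healthy GMP (0) to healthy DN2 (1), the lineage genes placed the DN2-labelled leukemias at 0.743 ± 0.0347 (SD, n = 5), the LSK-labelled at 0.139 ± 0.0456 (SD, n = 3) and the GMP-labelled at 0.0430 ± 0.0276 (SD, n = 5). The 559 genes higher in healthy DN2 placed the DN2-labelled leukemias at 0.553 and the 513 genes higher in healthy GMP at 0.909. The high T-cell genes and low granule genes of these arrays themselves move the position, so it does not tell the cell of origin from that pattern. On these 2 sides the LSK-labelled leukemias lay at 0.136 ± 0.0417 and 0.142 ± 0.122 (SD, n = 3) and the GMP-labelled at −0.0452 ± 0.0333 and 0.120 ± 0.0303 (SD, n = 5). In 1 simulation, GMP-labelled, LSK-labelled and DN2-labelled arrays placed at 0.1, 0.2 and 0.3 were recovered at 0.1525, 0.2453 and 0.3237. Low positions thus read too high in that simulation. Positions near 0.743 were not simulated, so the direction of any error there is not known. The DN2-labelled and GMP-labelled arrays differed by 0.700 (exact permutation p = 0.0079). The DN2-labelled and LSK-labelled differed by 0.604 and the LSK-labelled and GMP-labelled by 0.0963 (exact permutation p = 0.0179 for each). Adjusted over the 3 pairs each exact p was 0.0179, the smallest the designs with 3 arrays allow. Without LSK-labelled array 1, the last difference was 0.0673 (exact permutation p = 0.0952). Of the genes that differed between DN2-labelled and GMP-labelled leukemia, 360 were higher both there and in healthy DN2 against GMP, where chance gives 141 (odds ratio 4.93, Fisher exact p = 1.51e-82). In both, 373 were lower, where chance gives 118 (odds ratio 7.39, Fisher exact p = 4.26e-120). In opposite directions 29 and 21 were shared, where chance gives 132 and 127. The 2 comparisons share no arrays, but both come from 1 fit with a shared spread per gene. Genes are not independent replicates, so these Fisher p-values do not measure the spread between samples. The 733 genes shared in the same direction became 350 without healthy DN2 replicate 1, 370 without replicate 2, 430 without healthy GMP replicate 1 and 326 without replicate 2. The 50 in opposite directions became 12, 13, 22 and 15.

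**Figure D4:**
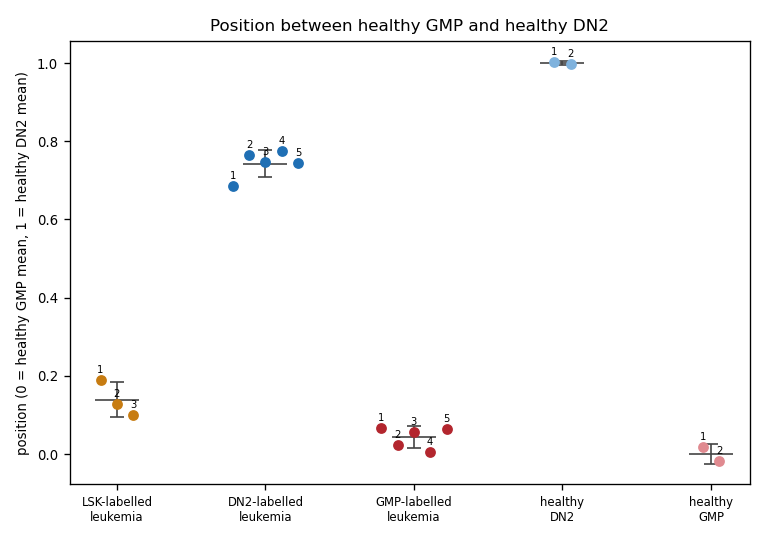
Position of each array (points with replicate numbers) between the healthy GMP mean (0) and the healthy DN2 mean (1) over 1072 lineage genes; bars are the group mean ± SD. The 5 DN2-labelled leukemias lie between 0.685 and 0.774, and every LSK-labelled and GMP-labelled leukemia lies at or below 0.190.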

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

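The tests of the low granule genes, of signal loss at the Mycn and Bcl2 probe sets and of a mixture of male and female cells were chosen only after the result was seen; the test for untransformed cells and the splits of the arrays were chosen before.

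Neutrophil granule genes lay far under the GMP-labelled level in all 5 DN2-labelled arrays, although the label names a sort for CD11b and Gr1, with traces in arrays 1 and 5 (S100a8 at 7.05 and 8.03, late neutrophil mean 5.32 and 4.76 against 3.97 in healthy DN2). Lymphoid cells admixed to a myeloid sort are argued against, for myeloid cells like those of the GMP-labelled arrays, because the median granule gene reached at most 0.972% of the GMP-labelled level in any of the 5. Labels exchanged with a healthy group of the series are argued against by Mycn, which was 11.58 in the lowest DN2-labelled array and 4.58 in the highest healthy array, and an exchange with another leukemia group of the series would leave the conflict with the sort in place, since all leukemia labels name it. Whether such an exchange decides which leukemia holds the granule genes stays open, because the 0 arrays of other groups with a late neutrophil mean under 6 and an NK mean over 7 are what an exchange of whole groups would leave too. In all 5 arrays Mpo was 3.35 to 3.67, against 7.71 to 13.36 in the GMP-labelled arrays. The T-cell receptor mean was 9.94 ± 0.13 (SD, n = 5), against 4.22 ± 0.09 in the GMP-labelled arrays. The RNA of all 5 thus had a lymphoid pattern, and how this pattern arose under this label stays open. A lymphoid fraction or leukemia hybridised under it was not told apart from the cell of origin, which the design names and which was not tested. Itgam does not decide between them. It lay at or below the higher healthy DN2 array (3.97) in 3 arrays, but at 7.17 and 7.38 in arrays 1 and 3. Those arrays also had the highest NK means (10.51 and 10.54 against 8.16 to 8.92), and array 3 had S100a8 at only 3.87.

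LSK-labelled arrays 2 and 3 had Mycn at 4.91 and 4.22 and Bcl2 at 6.75 and 5.27, against 12.82 and 11.30 in array 1. Mostly untransformed cells in these arrays were tested on 153 genes raised in both other leukemia groups, and the arrays lay at 1.25 and 1.22 on the way from healthy (0) to leukemia (1), which met the bound of 0.8 written in advance against this explanation. Only after the result was seen was the test judged unable to decide, because GMP-labelled arrays 4 and 2, with Mycn at 12.06 and 12.79, scored lowest (0.654 and 0.801) and the healthy arrays hold progenitors of other tissues, not mature spleen cells. Loss of signal at these probe sets alone is argued against, since the higher ribosome biogenesis mean of the 2 arrays differed by −1.73 from the lowest of the other 11 leukemia arrays. Untransformed cells stay open. Cdkn2a at 3.70 and 3.75 and p53 pathway means of 7.12 and 6.70 in arrays 2 and 3 were nearer to healthy cells than array 1 (10.34 and 8.67). The second Bcl2 probe set was 9.32 and 8.48 in them and 6.90 in array 1, against 8.62 to 9.84 in healthy cells. Myc, in contrast, was 6.13 and 5.95 in them, against 10.10 to 10.65 in healthy cells. These healthy cells are progenitors, so the comparisons with them do not decide either way. Cdkn2a was also 3.77 in a DN2-labelled array with Mycn at 12.10, and the DN2-labelled p53 pathway mean was 7.46 ± 0.26 (SD, n = 5). The cell cycle mean was 8.71 ± 0.33 in the LSK-labelled (SD, n = 3) and 8.94 ± 0.42 in the GMP-labelled arrays (SD, n = 5). The LSK origin was not tested.

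LSK-labelled array 3 carried Xist at 10.92 together with the Y-linked Eif2s3y at 8.93, while Eif2s3y was at most 3.03 in 12 other arrays and Xist 4.53 to 6.84 in the 4 other arrays with Eif2s3y at 9.60 or more, of which DN2-labelled array 2 (6.34) and GMP-labelled array 2 (6.84) also carried some Xist signal. A mixture of male and female cells would need the 2 shares to add up to about 100%, and the median Y-linked share and the Xist share summed to 66.4%, within the range set for it (60 to 140) but near its lower end. The Y-linked genes differed among themselves, with shares of 51.8% (Eif2s3y), 29.4% (Kdm5d) and 18.2% (Uty), so the mixture is at most a possible explanation. Donor and recipient cells of unlike sex and RNA mixed in handling were not told apart, and no biological explanation was tested.

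For the 3 counts between leukemia groups, no other split tried gave as many genes as the real one. Splits that mix the groups put the large difference between them into the spread, so few calls were likely in advance. The splits also treat replicates as separate samples, which the labels do not state, so chance is not excluded. The other 5 counts each involve a group of 2 arrays and had no splits. Of 100 drawn splits of the DN2-labelled and GMP-labelled arrays 1, the real one, gave as many genes (4628; highest other 220). The same held for 1 of 56 splits of the DN2-labelled and LSK-labelled arrays (5514; highest other 892) and 1 of 56 of the LSK-labelled and GMP-labelled arrays (3108; highest other 1128).

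In 70 series of 5 arrays, a highest or lowest value far from the other 4 was found 11 times, where chance gives about 1 in 20, or 3.5. The series are not independent: 6 of the 11 are sex-linked values of 2 arrays, so these counts overstate any excess. DN2-labelled array 2 stood apart in Eif2s3y at 10.05 (others 2.72 to 2.92), in Xist at 6.34 (others 12.24 to 12.54) and in the mean of sex-linked genes at 7.68 (others 5.36 to 5.53). GMP-labelled array 2 stood apart in the same 3, with Eif2s3y at 9.90 (others 2.75 to 2.84), Xist at 6.84 (others 11.85 to 12.92) and sex-linked genes at 7.24 (others 5.36 to 5.60), and in erythroid genes at 5.59 (others 4.34 to 4.57). The mean of myeloid transcription factors was 8.02 in DN2-labelled array 1 (others 6.85 to 7.12) and 9.30 in GMP-labelled array 4 (others 8.29 to 8.48). Primary granule genes were at 5.06 in DN2-labelled array 5 (others 4.76 to 4.81), and recombination genes at 5.37 in GMP-labelled array 1 (others 5.69 to 5.79). The effects of leukemia against healthy cells differed between DN2 and GMP in 1473 genes by the test of the interaction itself.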

How the results depend on the processing

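Leaving out LSK-labelled arrays 2 and 3 together and the Y-linked covariate were chosen only after seeing the data; all other alternatives were fixed before. Unless the construction is named, the cause of a change was not tested. Counts are in the order DN2-labelled minus GMP-labelled, DN2-labelled minus LSK-labelled, LSK-labelled minus GMP-labelled, DN2-labelled minus healthy DN2, GMP-labelled minus healthy GMP, healthy DN2 minus GMP, DN2-labelled minus healthy GMP, and the interaction.

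The 8 counts stayed within 1.5 times of the reported value without the filter or with a stricter one, with the mean of a gene's probe sets, with other prior variances, with repeated scaling and with the Y-linked covariate. Counting probe sets, of which there are more than genes, gave 8655, 10618, 5595, 5084, 4098, 2200, 7154 and 2271. A fold of at least 2 lowered the first 3 to 2762, 3490 and 1867. An adjusted p under 0.01 lowered the last 6 to 1750, 1576, 1160, 718, 2353 and 761. Array weights raised the last 5 to 5885, 6054, 5439, 6249 and 5243. With only the groups compared in the fit, LSK-labelled minus GMP-labelled fell to 1659 and healthy DN2 minus GMP rose to 5326. Without LSK-labelled arrays 2 and 3 the counts against the DN2-labelled and GMP-labelled leukemias were 3172 and 1374.

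Leaving out 1 replicate at a time, the first 2 counts stayed within 1.5 times, at 4149 to 4622 and 4576 to 5614. The others ran from 1889 to 3716, 1236 to 2676, 848 to 3342, 602 to 785, 1954 to 3778 and 782 to 1749. Genes shared between the leukemia and healthy comparisons ran from 326 to 792 in the same direction and from 12 to 72 in opposite directions. The LSK-labelled and GMP-labelled positions differed by 0.0673 to 0.120, not past the threshold without LSK-labelled array 1. The within-group correlations kept their direction and side of the threshold in every alternative.

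Replicate numbers were not taken to pair the samples, since of 25 pairs of arrays with the same number only 6 had r over 0.1 (range −0.302 to 0.254). The own number was the best match in 26 of 50 cases, where chance gives 16.1. Y-linked Eif2s3y was high in array 2 alone among the DN2-labelled (10.05) and among the GMP-labelled arrays (9.90). It was also high in every LSK-labelled array (8.93 to 9.90) but not in array 2 of healthy DN2 (2.69) or GMP (3.03). Some structure shared by number is therefore not excluded. A replicate block left all counts within 1.5 times (4595, 4972, 2561, 2447, 2418, 1222, 3593 and 1402). The 3 position differences were then 0.700 (exact p = 0.0625), 0.593 (exact p = 0.25) and 0.0903 (exact p = 0.25), the smallest p that sign flips over so few numbers can give.

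With an estimated correlation 2, 2, 0, 1, 3, 6, 4 and 1 lists were called, against 8, 13, 10, 6, 7, 10, 12 and 10 with the preset one. Fry called 13 in DN2-labelled minus GMP-labelled and 11 in DN2-labelled minus healthy DN2.

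For 866 pairs of named gene and comparison, 17112 of 18363 alternatives kept direction and side of the threshold, 856 lost the call, 383 gained one and 12 reversed. With the mean of its probe sets, which disagree, Bcl2 was 0.71 in LSK-labelled minus GMP-labelled and −0.19 in GMP-labelled minus healthy GMP, and Ms4a6c was 1.24 in DN2-labelled minus healthy GMP. Without LSK-labelled arrays 2 and 3, Bcl2 was −1.62 in DN2-labelled minus LSK-labelled, and in LSK-labelled minus GMP-labelled Bcl2 was 0.54 and Perp 0.52. The Y-linked covariate is built from Eif2s3y alone, as present or absent in each array. It reversed Eif2s3y and the Y-linked Kdm5d and Uty. They were then 0.53, 1.10 and 1.57 in DN2-labelled minus LSK-labelled, and −0.46, −1.13 and −1.30 in LSK-labelled minus GMP-labelled.

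Where leaving out arrays leaves 1 in a group (each healthy group, and LSK-labelled array 1), that array is assumed to vary like the other groups, and the smaller group alone lowers counts. Signal close to background compresses differences, and genes with no group mean above 3.83 were not tested. Other probe sets of 7, 22, 4, 9, 2, 0, 11 and 2 genes were called by limma in the opposite direction. The table holds no detection calls, and the authors' normalization could not be repeated from raw signal here.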

Other observations

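The test of a single donor clone was chosen only after the result was seen, as were the arrays and genes singled out here.

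Bcl2l11, Bbc3 and Pmaip1, which promote apoptosis, were each higher in both leukemias than in their healthy cells; they were picked from the Bcl2 family after their values were seen. Against healthy DN2 the DN2-labelled leukemia had Bcl2l11 higher by 3.77 ± 0.45 (SE, n = 5 and 2, limma adjusted p = 2.10e-05), Bbc3 by 2.98 ± 0.56 and Pmaip1 by 2.53 ± 0.61, whereas Bcl2l2, which counters apoptosis, differed by −2.30 ± 0.31. Against healthy GMP the GMP-labelled leukemia had Bmf higher by 3.99 ± 0.62 (SE, n = 5 and 2, limma adjusted p = 4.17e-04), Bbc3 by 3.43 ± 0.56, Bcl2l11 by 3.05 ± 0.45 and Pmaip1 by 2.01 ± 0.61. The Bcl2 family was called as a list in neither comparison (3 of 12 higher, 2 lower, the same counts adjusted over the list alone, adjusted p = 0.697; 4 higher, 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.204), and these 3 genes were not tested as a set.

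GMP-labelled arrays 2 and 4 stood apart from the other 3 at progenitor genes. Mpo was 13.34 and 13.36 in them and 7.71 to 8.87 in the other 3, Cebpa 7.87 and 8.35 against 3.78 to 4.41, and Kit 6.81 and 6.67 against 3.18 to 3.30. Cdkn2a, a cell cycle inhibitor, was 10.34 in LSK-labelled array 1 and 3.70 and 3.75 in arrays 2 and 3. In the GMP-labelled arrays Cdkn2a was 8.97, 4.68, 8.48, 5.44 and 8.37 in replicate order, and in healthy DN2 and GMP it had means of 3.38 and 3.41. Epcam, a gene of epithelial cells, had a mean of 9.82 ± 0.18 in the DN2-labelled arrays (SD, n = 5) and 6.42 ± 0.22 in healthy DN2 (SD, n = 2).

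Penk was high in all 5 GMP-labelled leukemias (9.78 ± 0.49, SD, n = 5) and had means of 3.61 to 4.34 in the other groups. One donor clone behind all 5 arrays could give such a gene, but Y-linked transcript was present in 1 of the 5 arrays and absent from the others. This argues against a single clone over all 5. A clone shared by the arrays without Y-linked transcript was not tested.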
